A study of Mus musculus with 8 samples.

How the data were processed

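RNA was measured in 8 libraries of mouse T cells sorted by flow cytometry as CD4-positive and Foxp3-positive, with a stranded poly(A) library kit, per the labels' protocols. The labels put 2 libraries in group T138, 3 in T143 and 3 in WT. T138 and T143 are mouse lines derived by somatic cell nuclear transfer, in which an animal is made from the nucleus of a single T cell, so that its T cells carry a rearranged receptor from that cell. Group and replicate were taken from the titles. The source name of T143 replicate 1 names a T138 mouse and that of WT replicate 1 a T143 mouse. Their titles, model labels and descriptions name the group used here. Nothing in the labels says more about the mice behind replicates, so p-values measure the spread between these libraries, which may be partly technical. All 8 libraries, WT included, carry the same strain label with a Rag1 knockout and a Foxp3 reporter. Whether the Rag1 label holds for the WT mice is not known. If it does not, Rag1 genotype cannot be told apart from line in the comparisons with WT.

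The deposited values are a signal: gene read counts that the authors divided by a factor per library, which brings every library to the same total (15.59 M). That description rests on the deposited values, which are whole multiples of a step per library. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2b, HOMER 4.8, edgeR without a version and the build mm10, with no role or order for any of them. The counting of strand, multi-mapped reads and duplicates is not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies such as the globins, are therefore uncertain. Gapdh was listed at low values, and it has many processed copies in the genome.

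Dividing each value by its step returned whole reads for 100% of values within 0.01 deposited units. The recovered library totals ran from 7.83 M (T143 replicate 1) to 22.64 M (WT replicate 1), with T138 at 15.84 and 18.41, T143 at 7.83, 12.25 and 12.6, and WT at 22.64, 14.64 and 20.51 M. A count of 3 reads, taken as the floor that a count of 0 allows, corresponds to a value between 2.07 and 5.97 depending on the library. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. Genes with 1 to 3 reads made up 10.91, 10.79 and 11.26% of detected genes in T143, 1.74 and 0.83% in T138, and 7.69, 2.11 and 4.93% in WT. A low percentage at these depths can come from few starting molecules amplified many times, which was not measured here. Read number may therefore overstate precision at low values in those libraries.

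Tests were run on log2(value + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend and robust fitting. A gene entered with a value of at least 1 in at least 2 libraries, which left 15547 of 24453. All 8 libraries were fitted together with group means and no covariate, because T138 has only 2 libraries and the groups then share an estimate of the spread. Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Quantile normalization moved the median log2 change of all genes from 0.152 to 0.014 for T143 against T138 and from 0.053 to -0.078 for T143 against WT, and changes are to be read relative to those medians.

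The 14 biology gene lists and the marker lists of other cell types were fixed before the data were examined, as were the tests, the named-gene rule and most alternatives. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A neutrophil granule list and an MHC class II list were added after the data were seen and are given as values. Named genes comprise 12 fixed genes, the 10 higher and 10 lower genes with the largest change (5 and 5 against WT) that passed the threshold, had a mean above the median of tested genes (310.4) and did not overlap between groups, up to 4 members of each list with the smallest p, and the 5 highest members of each marker list as values. T cell receptor and immunoglobulin segments, predicted genes and small RNA names were excluded from the ranking. Some genes that met the rule are not reported here. Receptor segment usage was planned but is not analysed here. Gene positions came from a RefSeq table of GRCm38 and transcript lengths from GENCODE transcript sequences of the same build. They were found for 24361 and 24221 of 24453 rows. Matching was by transcript identifier (24197 and 23878 rows) and otherwise by symbol.

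The limma procedure was tested on simulated counts drawn from the libraries' means, depths and dispersions, with 100 genes changed at each fold size. The changed genes were drawn only from genes above a minimum mean, so recovery of low genes was not measured. For T143 against T138 it recovered 81% of 4-fold and 19% of 2-fold changes, with 8.3% of calls false. The corresponding values were 86, 30 and 12.1% for T138 against WT and 80, 39 and 1.7% for T143 against WT. Absence of a call is therefore weak evidence at 2-fold, and the false share exceeded the nominal 5% in both comparisons with T138. Each share came from a single simulated data set, so its spread is not known. Alternatives changed the scaling, pseudocount, filter, trend, samples and fold threshold, and left out each library. Added after seeing the data were edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, TMM scaling, removal of a transcript length trend, a filter at 100, a myeloid covariate and omission of the libraries with the most neutrophil signal in each line. Within-group pairs were neither identical nor within sampling noise. Figures were drawn with matplotlib 3.10.9.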

Results

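The series compared regulatory T cells (Treg cells) of 2 mouse lines made by somatic cell nuclear transfer, T138 and T143, with each other and with wild-type (WT) cells, to ask whether the lines represent distinct Treg subsets. Per the series description, T138 is a model of naturally occurring Treg cells and T143 a model with agonist-induced development. Messenger RNA of CD4-positive, Foxp3-positive sorted T cells was sequenced in 2 T138, 3 T143 and 3 WT libraries. Recovered depth was 15.84 and 18.41 M reads in T138, 7.83, 12.25 and 12.6 in T143, and 22.64, 14.64 and 20.51 in WT. Values below are normalised read counts as mean ± SD, and changes are on the log2(value + 1) scale with SE.

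The groups parted on the first and second principal components. The first principal component (39.0% of variance) placed the T143 libraries at scores of -54 to -129.5 and WT at 87.5 to 103.6, and the second (24.8%) placed T138 at -107.1 and -131.1. The third (11.3%) spread the WT libraries, at 97.6, -84.1 and -15.9. The first component also ran with the mean log2 level of the myeloid markers. That level was 10.41, 11.95 and 12.91 in T143, 10.13 and 9.19 in T138, and 5.3, 5 and 4.8 in WT. The first component therefore cannot be read as a difference of Treg cells alone. Pearson correlation of log2 values was 0.93 to 0.973 within groups and 0.846 to 0.924 between groups. Over the 1000 genes with the highest variance it fell to 0.463 within WT, against up to 0.441 between T138 and T143. T143 replicate 1 and WT replicate 1, whose source names point to another mouse, lay with the group of their titles. Without both, 2765 genes passed for T143 against T138, 1386 for T138 against WT and 2818 for T143 against WT, where the balance turned to 1584 higher and 1234 lower. No list that passed with or without them changed direction. Glycolysis lost its call for T143 against WT, and receptor complex genes (T143 against WT), T helper genes (T143 against T138) and cell cycle genes (T138 against WT) each passed as lower.

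**Figure D1:**
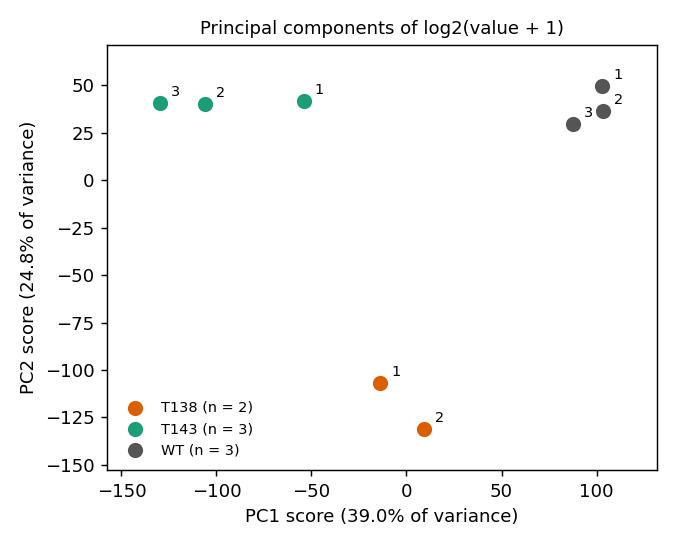
Scores of the 8 libraries on the first and second principal components of log2(value + 1), with 1 point per library numbered by replicate and coloured by group. T143 and WT part along the first component (39.0% of variance), and the 2 T138 libraries lie apart on the second (24.8%). The first component also runs with the myeloid marker level.

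The sorted fractions differed in transcripts of other cell types and in sex. S100a9, a member of the added neutrophil list and of the myeloid marker list (chromosome 3, 90692630 to 90695721, GRCm38), was at 7989 and 1218 in T138, 31220, 51230 and 198600 in T143, and 33.75, 14.91 and 4.56 in WT. The added neutrophil granule list took 0.168 and 0.0311% of signal in T138, 0.652, 1.11 and 4.02% in T143, and at most 0.00644% in WT. MHC class II genes of antigen-presenting cells were highest in T138, with H2-Aa at 20490 and 14710 in T138, 1194, 5468 and 3886 in T143, and 365, 95.85 and 140.6 in WT. The dendritic cell marker Itgax was at 3851 and 3803 in T138, 173.1, 604.5 and 678.2 in T143, and 10.33, 135.2 and 34.2 in WT. All 9 tested erythroid genes were higher in T143 than in WT and 3 of 9 higher than in T138. Slc4a1 was at 266.7, 2417 and 1507 in T143, 20.67 and 184.6 in T138, and 29.62, 42.6 and 17.48 in WT, while Hbb-bs at 814.5 in T138 replicate 2 was close to 817.9 in T143 replicate 1. Xist, transcribed from the inactive X chromosome of females (X, 103460373 to 103483233), was at 19140, 24990 and 24140 in T143, where the Y-linked genes Eif2s3y and Kdm5d were at 0 in every library. In T138 Xist was at 2.95 and 0, and Ddx3y was at 3634 and 3175. WT had Ddx3y at 2923, 3018 and 2094. Sex-linked transcripts thus parted every T143 library from every library of the other groups.

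**Figure D2:**
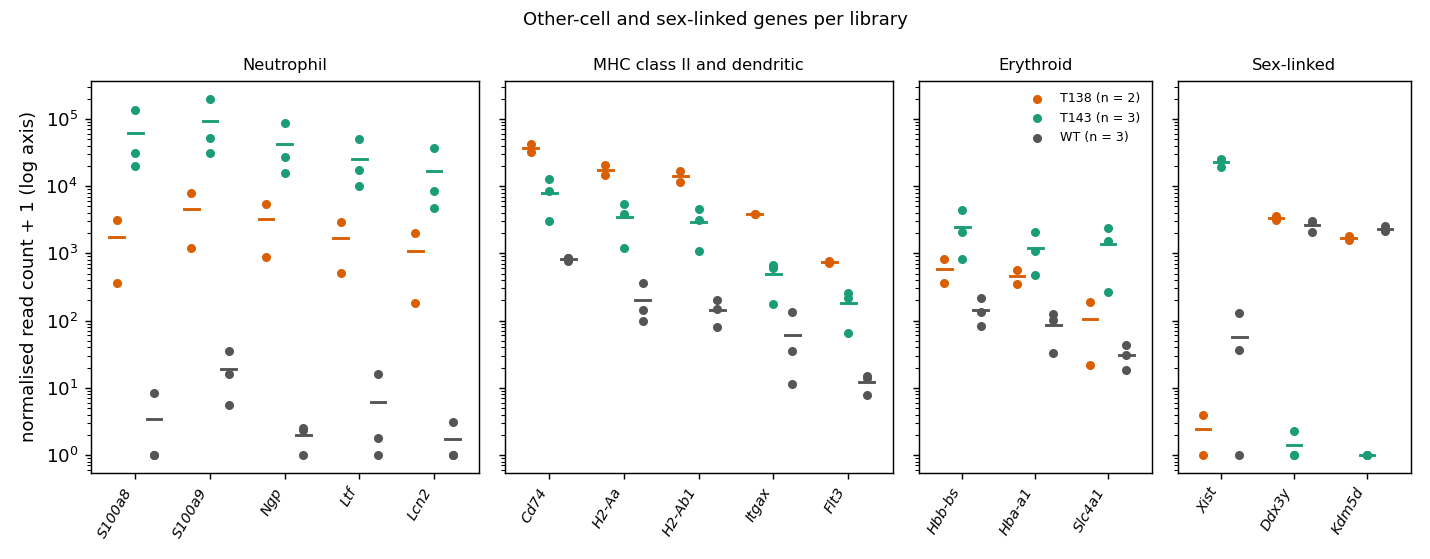
Normalised read count + 1 on a log axis for genes of other cell types and sex-linked genes, with 1 point per library and a bar at the mean of each group. S100a9 lies between 31220 and 198600 in T143 and at no more than 33.75 in WT, while H2-Aa is highest in T138 (20490 and 14710).

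The main comparison asked how T143 differs from T138. Foxp3, which encodes the transcription factor that defines Treg cells (X, 7579676 to 7595243), was at 41510 ± 489.9 in T138 (n = 2) and 6305 ± 2387 in T143 (n = 3), a log2 change of -2.79 ± 0.27 (limma, adjusted p = 0.000206). Cd4, on which the cells were also sorted, was at 12530 ± 413.7 and 13240 ± 2531 (log2 change 0.06 ± 0.17, adjusted p = 0.815). Of the 24 genes of the Treg core list, 15 were lower and 1 higher in T143, with the same numbers when adjusted over the list alone. In the same comparison 5 of 8 markers of conventional CD4 T cells were higher and 1 lower (median log2 change 3.06), and 5 of the 8 are also in the Resting T cell list. Il2ra, the high-affinity interleukin-2 receptor chain (chromosome 2, 11642792 to 11693194), fell (log2 change -2.72 ± 0.19, adjusted p = 2.69e-05). The inhibitory receptor gene Ctla4 also fell (-3.39 ± 0.57). Changes were -2.33 ± 0.24 for Ikzf2 (Helios), -2.64 ± 0.25 for Nrp1 and -3.23 ± 0.23 for Nt5e (CD73). Socs2, a feedback regulator of cytokine signalling, was at 56.72 ± 15.61 in T143 and 1546 ± 229.2 in T138. The list was lower by camera (adjusted p = 5.32e-11), a call lost with an estimated correlation (adjusted p = 0.181).

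Genes of resting and of effector cells moved in opposite directions. In the Resting T cell list 15 of 20 genes were higher in T143 and 1 lower (16 and 1 adjusted over the list alone). Tcf7, a transcription factor gene of resting and memory T cells (chromosome 11, 52246527 to 52283383), was at 25750 ± 6687 in T143 and 2606 ± 379.7 in T138 (log2 change 3.28 ± 0.21). The chemokine receptor gene Ccr7 rose by 3.79 ± 0.42 and the chromatin organiser gene Satb1 by 3.2 ± 0.22. Il7r was the member that fell (-2.1 ± 0.16). In the Effector Treg list 12 of 26 were lower and 0 higher (15 and 0 adjusted over the list alone), among them Il1rl1, the interleukin-33 receptor (chromosome 1, 40404864 to 40465418), at 1091 ± 228.1 in T143 and 20720 ± 498.6 in T138 (-4.27 ± 0.4). Klrg1 (-2.76 ± 0.3), Gata3 (-2.48 ± 0.15) and Rora (-2.97 ± 0.3) fell as well. Camera gave adjusted p = 1.93e-09 for the resting and 6.83e-09 for the effector list, and with an estimated correlation adjusted p = 0.181 and adjusted p = 0.299. MHC class II transcripts were higher in T138 and neutrophil transcripts in T143 in the same libraries.

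Among lists of inducible genes, NF-kB targets held 11 lower and 0 higher of 17 in T143 (12 and 0 adjusted over the list alone), with Tnfaip3, an inhibitor of NF-kB (chromosome 10, 19000910 to 19015410), at 1864 ± 85.51 in T143 and 24670 ± 1320 in T138 (-3.73 ± 0.15, adjusted p = 3.26e-07). Nfkbia changed by -1.74 ± 0.18. The immediate early and heat shock list held 9 lower and 1 higher of 20 (11 and 2 adjusted over the list alone), with changes of -5.93 ± 0.38 for Fosb and 1.12 ± 0.16 for the chaperone gene Hspd1. The TCR signal response list was divided, with 8 lower and 5 higher of 24 (10 and 5 adjusted over the list alone). Dusp5 changed by -3.25 ± 0.21 and Egr1 by -1.73 ± 0.16, while the nuclear receptor gene Nr4a3 was at 394.2 ± 129.4 in T143 and 22.62 ± 11.12 in T138 (4.09 ± 0.4). Camera placed these lists lower with adjusted p = 9.49e-09, 1.32e-05 and 0.0077, and each had adjusted p = 0.181 with an estimated correlation.

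Cell cycle genes were higher in T143, with 9 of 29 higher and 0 lower (9 and 0 adjusted over the list alone), for example Mcm2 (1.45 ± 0.21) and Pcna (1.12 ± 0.21). Cholesterol synthesis held 8 higher and 1 lower of 20 (9 and 1 adjusted over the list alone), with Hmgcs1 at 1.35 ± 0.23 and Sc5d at -1.31 ± 0.17. Camera gave adjusted p = 2.19e-06 and 0.00115, and with an estimated correlation adjusted p = 0.459 and adjusted p = 0.221. Fry gave adjusted p = 0.0951 and 0.0184, so the cell cycle list lost its call there too. Neutrophil transcripts were also higher in these T143 libraries. Follicular (3 of 12 higher, 2 lower), T helper (1 of 17 higher, 7 lower), interferon (3 of 26 higher, 1 lower), glycolysis (5 of 16 higher), homing (4 of 28 higher, 12 lower) and receptor complex genes (5 of 16 higher, 1 lower) did not pass as lists, with camera adjusted p = 0.486, 0.0519, 0.541, 0.0879, 0.089 and 0.5. The T helper and homing lists had medians of -0.4 and -0.33 but means of 0.11 and 0.17. T helper genes passed as lower without T138 replicate 1 (0.0405), T143 replicate 3 (0.0108), WT replicate 1 (0.0308) or WT replicate 3 (0.0493). Without T143 replicate 3 homing genes passed as lower (0.043) and interferon genes as higher (0.0421), and without T143 replicate 2 glycolysis passed as higher (0.0212).

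In all, 3272 of 15547 genes passed for T143 against T138, 1681 higher and 1591 lower, with edgeR on recovered reads calling 2907. The balance depended on scaling, with 1272 higher and 1713 lower after median centring and 1587 and 1852 after quantile normalization. The count was 1347 without T138 replicate 2, 2046 without T138 replicate 1, 2004 without T143 replicate 2, and 1676 without both T138 replicate 1 and T143 replicate 3, which had the most neutrophil signal of their groups. With the myeloid marker level as a covariate, added after seeing the data, 1174 genes passed. Genes named for the largest rises in T143 included S100a8, Abca13, F13a1, Mgst1, Serpinb1a and Wfdc21. Each rose from T143 replicate 1 to 3, in the order of the neutrophil signal. S100a8 was at 19720, 31390 and 134800 there, and Serpinb1a at 431.8, 1026 and 5472. The rises of these genes cannot be read as changes of Treg cells.

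**Figure D3:**
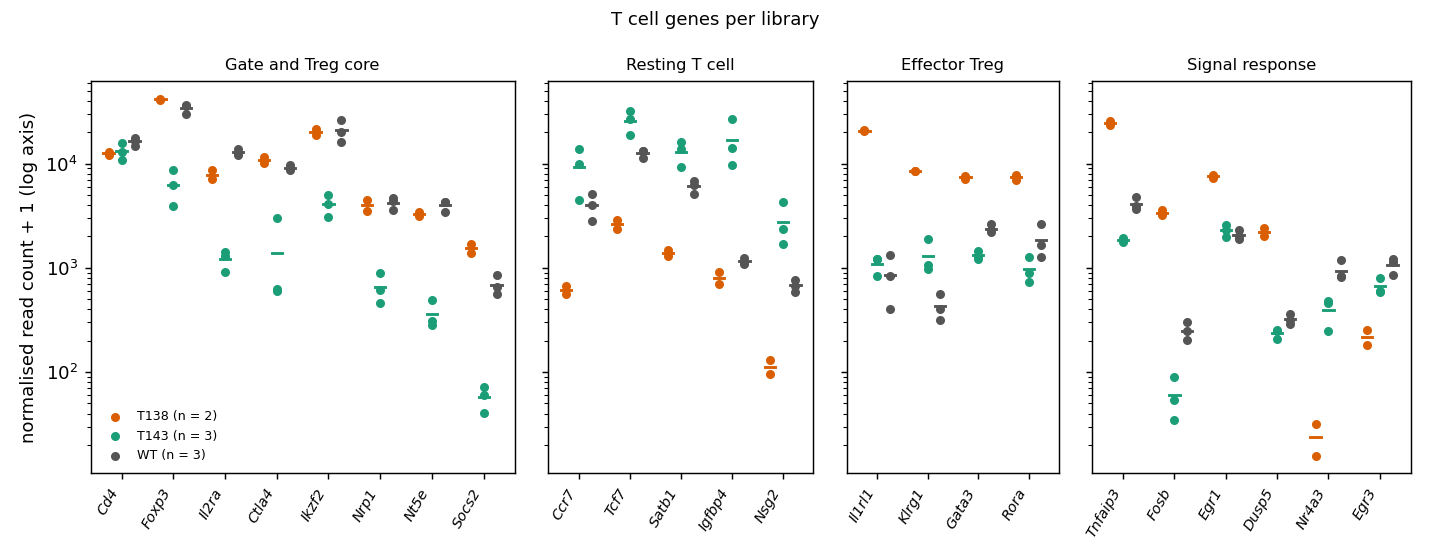
Normalised read count + 1 on a log axis for T cell genes, with 1 point per library and a bar at the mean of each group (T138 n = 2, T143 n = 3, WT n = 3). Foxp3 lies at 3920 to 8694 in T143 and at 29770 to 41850 in the other groups, whereas Tcf7 is lowest in T138.

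T138 was next compared with WT. Foxp3 was at 41510 ± 489.9 in T138 (n = 2) and 33830 ± 3550 in WT (n = 3), a log2 change of 0.3 ± 0.27 that did not pass (limma, adjusted p = 0.542). Effector genes were higher in T138, with 12 of 26 higher and 1 lower (15 and 1 adjusted over the list alone). Il1rl1 was at 20720 ± 498.6 against 849.1 ± 454.8 (4.77 ± 0.4, adjusted p = 0.000195), Klrg1 rose by 4.35 ± 0.3, Fgl2 by 4.53 ± 0.38 and Gata3 by 1.64 ± 0.15. Resting genes went the other way, with 11 of 20 lower and 2 higher (12 and 6 adjusted over the list alone): Tcf7 changed by -2.28 ± 0.21, Bcl2 by -2.16 ± 0.17 and Bach2 by -3.26 ± 0.33, while Il7r rose by 2.73 ± 0.16. Camera gave adjusted p = 2.52e-09 and 0.000247, and both had adjusted p = 0.533 with an estimated correlation. In the same T138 libraries 6 of 10 dendritic, 7 of 7 MHC class II, 12 of 14 myeloid, 11 of 15 neutrophil granule and 5 of 10 natural killer cell markers were higher. Fgl2 was at 4613 and 3279 in T138 and 662.7, 1425 and 1330 in T143. Within each line, but not within WT, this was the order of the MHC class II gene H2-Aa. Its rise may therefore not be one of Treg cells.

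The immediate early and heat shock list was higher in T138 than in WT, with 10 of 20 members higher and 1 lower (12 and 1 adjusted over the list alone). Of its 7 heat shock members 0 were called higher and 1 lower, so the higher calls were all among the 13 immediate early members. Fosb was at 3393 ± 253.6 against 249.3 ± 50.81 (3.78 ± 0.38), Egr1 rose by 1.87 ± 0.16 and Zfp36, which destabilises cytokine mRNA, by 2.06 ± 0.2. The list had camera adjusted p = 1.35e-06, and adjusted p = 0.533 with an estimated correlation. Members of the TCR signal response list went both ways, with 3 of 24 higher and 7 lower (4 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.167). Dusp5 rose by 2.8 ± 0.21, whereas Nr4a3 changed by -5.38 ± 0.4, Egr2 by -1.94 ± 0.26 and Egr3 by -2.3 ± 0.24. The Treg core list did not pass (adjusted p = 0.161), with 8 of 24 lower and 1 higher (8 and 3 adjusted over the list alone). Its member Gpr83 was at 336 ± 122 in T138 and 5960 ± 844.7 in WT, and Izumo1r, Ikzf4 and Tnfrsf9 changed by -2.16 ± 0.26, -1.51 ± 0.22 and -2.06 ± 0.25. Homing genes went both ways, with a change of 4.01 ± 0.44 for Ccr2.

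The follicular list was lower in T138 (5 of 12 lower, 0 higher, camera adjusted p = 0.000286, estimated correlation adjusted p = 0.533). The receptor complex list was lower (5 of 16, adjusted p = 0.0255) and the interferon list higher (2 of 26, adjusted p = 0.0332), with estimated correlation adjusted p = 0.631 and adjusted p = 0.68. Without T138 replicate 1 neither passed (adjusted p = 0.127 for each), and the interferon list did not pass without T143 replicate 3 (0.0586) or WT replicate 2 (0.179). With the myeloid marker level as a covariate the receptor complex list was higher instead (adjusted p = 0.00211), and the resting list changed direction without passing (0.327). T helper genes (3 of 17 higher, 1 lower), NF-kB targets (4 of 17 higher, 2 lower), cholesterol synthesis (1 of 20 higher, 2 lower), cell cycle and glycolysis (0 called in each) and homing genes (8 of 28 higher, 7 lower) did not pass as lists, with camera adjusted p = 0.517, 0.269, 0.161, 0.21, 0.894 and 0.188. Without WT replicate 1 the cell cycle list passed as lower (9.95e-06), and without WT replicate 2 cholesterol synthesis did (0.0244). In all, 1716 genes passed, 892 higher and 824 lower. The count was 1001 without T138 replicate 1, 757 without T138 replicate 2 and 1096 without WT replicate 3. With the myeloid marker level as a covariate 1 gene passed adjustment in limma and 1423 had an unadjusted p under 0.05; without it edgeR, DESeq2 and limma-voom on recovered reads called 1398, 2290 and 1580.

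T143 was also compared with WT. Treg core genes were lower, with 20 of 24 lower and 0 higher (22 and 0 adjusted over the list alone). Foxp3 was at 6305 ± 2387 in T143 (n = 3) and 33830 ± 3550 in WT (n = 3), a log2 change of -2.49 ± 0.24 (limma, adjusted p = 0.000117). Il2ra changed by -3.43 ± 0.17, Ikzf4 by -3.52 ± 0.19, Nt5e by -3.5 ± 0.2 and Socs2 by -3.59 ± 0.27. The TCR signal response list held 14 lower and 0 higher of 24 (18 and 0 adjusted over the list alone), with changes of -1.05 ± 0.15 for Nr4a1 and -1.94 ± 0.22 for Tnfrsf9. NF-kB targets held 11 lower and 0 higher of 17 (13 and 0 adjusted over the list alone), with Cd83 at 230.9 ± 67.8 against 2289 ± 429.8. Camera gave adjusted p = 2.43e-18, 4.38e-08 and 4.38e-08. With an estimated correlation these had adjusted p = 0.0918, 0.0389 and 0.0918, so that the TCR signal response list kept its call. That list shares Tnfrsf4, Tnfrsf9 and Tnfrsf18 with the Treg core list and Nfkbie with the NF-kB targets. The lists are therefore not separate results.

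Resting genes were higher in T143 than in WT, with 10 of 20 higher and 1 lower (14 and 1 adjusted over the list alone). Igfbp4, a gene of resting CD4 T cells, was at 16900 ± 8898 against 1156 ± 86.72 (3.74 ± 0.3), Dapl1 rose by 6.62 ± 0.59 and Nsg2 by 1.94 ± 0.3. The Effector Treg list did not pass (adjusted p = 0.919), with 7 higher and 6 lower of 26 (7 and 7 adjusted over the list alone). In the T helper list, which did not pass (adjusted p = 0.188; 4 of 17 lower, 0 higher), Ccr6 changed by -2.73 ± 0.45. Cell cycle held 4 higher of 29 (2 adjusted over the list alone), among them Mcm2 (0.85 ± 0.18) and Pcna (0.94 ± 0.19). Camera gave adjusted p = 3.71e-05 for resting and 1.67e-05 for cell cycle genes, and with an estimated correlation adjusted p = 0.572 and adjusted p = 0.636. The interferon list was higher by camera (6 of 26 higher, 1 lower, adjusted p = 0.0232, estimated correlation adjusted p = 0.685), with Oasl2 at 2.97 ± 0.38. This list did not pass without T143 replicate 1 (0.0705), T143 replicate 2 (0.2) or WT replicate 2 (0.0791). Follicular genes were lower (2 of 12, adjusted p = 0.0232), and glycolysis (4 of 16, adjusted p = 0.0416) and cholesterol synthesis (4 of 20 and 0 adjusted over the list alone, adjusted p = 0.0324) were higher, with estimated correlation adjusted p = 0.636, adjusted p = 0.636 and adjusted p = 0.612. The follicular call was lost without T143 replicate 1 (0.0572), T143 replicate 2 (0.13) or WT replicate 3 (0.0653), and the cholesterol call without T143 replicate 3 (0.059) or WT replicate 2 (0.094). Glycolysis lost its call without T138 replicate 1 (0.0515), T138 replicate 2 (0.0538), T143 replicate 1 (0.0572), T143 replicate 3 (0.195), WT replicate 1 (0.0664) or WT replicate 2 (0.118). Immediate early and heat shock (3 of 20 higher, 2 lower), homing (7 of 28 higher, 6 lower) and receptor complex genes (3 of 16 higher, 5 lower) did not pass as lists (adjusted p = 0.667, 0.938 and 0.188). Without T143 replicate 3 the T helper list passed as lower (0.0401), as did the receptor complex list without T143 replicate 1 (0.0308).

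In these libraries all 14 myeloid markers and all 9 tested erythroid markers were higher than in WT. In all, 3698 genes passed, 1818 higher and 1880 lower. The balance depended on scaling, with 1403 higher and 2157 lower after median centring and 1974 and 1729 with TMM factors. Without T143 replicate 2 the count was 2426. With the myeloid marker level as a covariate 0 passed adjustment in limma and 1379 had an unadjusted p under 0.05. Without it edgeR, DESeq2 and limma-voom on recovered reads called 3440, 4248 and 3026. With the covariate the receptor complex list turned from lower to higher and passed (adjusted p = 1.75e-05). The cell cycle, glycolysis and cholesterol lists changed direction without passing (0.582, 0.34 and 0.944), as did Mcm2 (log2 -0.08).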

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

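The gene and list comparisons and the count over other splits of the libraries were fixed before the data were examined, and the tests of explanations below were chosen after the results were seen. For T143 against WT, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many genes as 3698, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05. Every other split also mixes T143 and WT libraries within a group, which puts their difference into the spread. Few calls then follow by design, so nothing is concluded from the contrast with 0.

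The named genes below and 1 list moved in opposite directions from WT in the 2 models, each passing against WT in both, and also passing for T143 against T138. That last change is the difference of the changes against WT, so for genes picked as opposed it is large by construction and is no independent evidence. The list, Resting T cell, passed in all 3 comparisons with camera at the preset correlation, and with fry for T143 against T138 (adjusted p = 0.00257) and T143 against WT (0.034) but not T138 against WT (0.0551). With an estimated correlation it had adjusted p = 0.533 for T138 against WT, 0.572 for T143 against WT and 0.181 for T143 against T138. Resting cell genes were lower in T138 and higher in T143: the log2 change from T138 to T143 was 2.92 for Actn1, 4.54 for Nsg2, 3.2 for Satb1 and 3.28 for Tcf7, and the median of the Resting T cell list was 2.46. The opposite held for Fosb (-5.93), Gata3 (-2.48), Nfkbid (-1.55), Nfkbiz (-1.91), Rora (-2.97), Socs2 (-4.77) and Tnfaip3 (-3.73). Across all genes tested, 90 were called against WT in opposite directions, 61 of them higher in T138 and 29 higher in T143. More genes were called in the same direction, with 457 higher in both lines and 288 lower in both.

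The Treg core list was lower in T143 than in WT, with Foxp3 at a log2 change of -2.49, a call lost with an estimated correlation (adjusted p = 0.0918). Dilution of WT-like Treg cells by Foxp3-negative CD4 T cells as the whole cause would lower no Treg gene further than Foxp3, since other cells can only add to a gene. Of 23 members 5 were lower relative to Foxp3: Lrrc32 at -2.77, Il2ra at -0.94, Nt5e at -1.01, Ikzf4 at -1.03 and Socs2 at -1.1. All members share the Foxp3 value of their library, which ran from 3920 to 8694 in T143, so they are not independent. The values argue against cells without Foxp3 as the whole cause, mainly through Lrrc32. Added cells with low Foxp3 are not covered. Dilution by myeloid cells is argued against by the T cell receptor complex list, whose median was -0.28 (SD 0.66). Foxp3-negative CD4 T cells as part of the cause stay open. Relative to Foxp3, 7 members were higher (Ebi3 at 2.41, for example), the direction that added cells would give. Of 8 conventional CD4 genes 6 were higher and 0 lower. However, 5 of the 8 are also in the Resting T cell list and only 1 of the other 3 was higher. Across T143 replicates 1 to 3 Foxp3 rose (3920, 6299 and 8694), while Igfbp4 (26840, 14160 and 9688), Dapl1, Satb1, Actn1 and Cd40lg fell. Il7r rose, Ifngr2 and Il2 did not fall steadily, and Cd4 also fell (15940, 12860 and 10920). The sort on Foxp3 should remove Foxp3-negative cells, although neutrophil transcripts were present after the same sort. Sex cannot be told apart from the line, since T143 libraries were all female-type and WT all male-type; 3.5% of calls and 3.44% of tested genes lay on X or Y, and a difference between the models is untested and also open.

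Neutrophil granule transcripts were present in the T138 and T143 libraries, although the sort on CD4 and Foxp3 should remove neutrophils. Other cells in the sorted fraction are a candidate source: all 15 genes of the list were higher in T138 replicate 1 than in replicate 2, with a median log2 ratio of 2.25 (SD 1.06), and in T143 replicate 3 than in replicate 1 (2.67, SD 0.48), while 7 MHC class II genes had 0.39 (SD 0.38) and 1.47 (SD 0.42). The T138 ratios ran from 0.27 for Ly6g to 3.44 for Lcn2, so the genes did not share 1 factor there, and a single uniform source is not shown. Reads of T143 libraries carried into T138 are argued against by Xist, at no more than 2.95 in T138 where the S100a9 shares of 8.53 and 1.3% would need 1941 and 296. Whether such cells differ in number between the models or between sorts was not tested.

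Immediate early genes were higher in T138 than in WT, with a median log2 change of 1.87 over 13 members. A transcript length bias is argued against, since the median was 1.89 (SE 0.75) with the length trend removed. Handling stress that also raises heat shock genes is argued against by 7 heat shock members with a median of -0.21 (SD 0.45), 0 of them called higher. Neutrophils are argued against by a median ratio of T138 replicate 1 to replicate 2 of 0.03 (SD 0.28) over the immediate early genes, compared with 2.25 for neutrophil genes. Dendritic cells, handling that spares heat shock genes and a difference between the models were not tested and stay open.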

How the results depend on the processing

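Tools on recovered reads, TMM scaling, the length trend, the filter at 100, the myeloid covariate and the omission of the libraries with the most neutrophil signal were chosen after seeing the data. No gene called both as reported and under an alternative changed sign. A reversal was counted only where the item was called as reported or under the alternative. The counts cover all genes picked by the naming rule, mentioned in the text or not, but not those left out of the reporting. Over the alternatives 5415 values kept their side of the threshold without a counted reversal, 509 lost a call, 16 gained one and 15 reversed. Of gene lists, 585 kept their side, 58 lost a call, 23 gained one and 6 reversed. Direction changes without a call in either fit were not counted. Examples are glycolysis for T138 against WT (higher by camera, lower by fry) and the Effector Treg list for T143 against WT (lower by camera, higher by fry). The counts of genes for T143 against T138, T138 against WT and T143 against WT were 1959, 872 and 2334 without the mean-variance trend and 1174, 1 and 0 with the myeloid covariate (unadjusted p under 0.05: 3548, 1423 and 1379 by limma). They were 1676 and 936 for the comparisons with T138 without the libraries with the most neutrophil signal, and 2052 and 2133 for those with T143 at an absolute log2 change of at least 1. Leaving out each library gave 1347 to 3668, 757 to 1779 and 2426 to 3558 genes. Counts moved over 1.5 times without T138 replicate 1 (2046 and 1001), T138 replicate 2 (1347 and 757), T143 replicate 2 (2004 for T143 against T138, 2426 for T143 against WT) and WT replicate 3 (1096). Without T138 replicate 1 or 2 the library left is assumed to vary like the other groups. Lists past the threshold were 0, 0 and 1 with an estimated correlation, and 7, 1 and 4 by fry. Of the 8 camera calls for T143 against T138, fry lost only cell cycle (adjusted p = 0.0951).

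All counted reversals among these genes and lists came with the myeloid covariate. For T138 against WT these were Cd28 0.13 and Lck 0.25, and the resting and receptor complex lists (direction 1). For T143 against WT they were Mcm2 -0.08, Mcm3 -0.26, Fdps -0.23, Hmgcs1 -0.34, Sqle -0.86, Klrg1 -0.04, Lgals3 -0.24, Aldoa -0.16, Gpi1 -0.53, Slc16a3 -2.29, Ccr1 -0.03, Ier3 -1.81 and Oas2 -0.47, the cell cycle, glycolysis and cholesterol lists (direction -1) and the receptor complex list (direction 1). Of the covariate's variance 94.9% lay between groups and the median SE grew 1.54, 2.78 and 4.33 times, so this covariate and the groups are nearly confounded. The cause of the changes was not tested otherwise. Replicate numbers showed no pairing, and a block on them gave 3109, 1804 and 3940 genes. With the block 1 list lost its camera call for T138 against WT, and 1 list gained one for T143 against T138. Depth limits low genes: 3 reads correspond to 2.07 to 5.97 in value.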

Other observations

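The shared-control and chromosome comparisons were chosen after the results were seen. Because T138 and T143 share the WT libraries, changes against WT correlate without any effect. Across genes, which are not independent replicates, r was 0.5348 against a mean of 0.445 in 50 simulations without effects, and covariance was 1.244 against 0.21. The share of genes with the same sign was lower than simulated, 59.07% against 64.6%. Genes higher in both lines numbered 457 (simulated 0, independent lists 104), those lower in both 288 (0 and 100), and those called in opposite directions 90 (0 and 204). Without effects almost no gene passes, so the simulated 0 was fixed in advance. The values for independent lists leave out the sharing of WT libraries. Neither gives the overlap that shared WT libraries produce among genes that do change, so nothing is concluded from these overlaps. The 3 WT libraries are too few to give each line its own controls.

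Rag1, a recombinase gene of developing lymphocytes (chromosome 2, 101638252 to 101649532, GRCm38), was at 108.3 and 106.7 in T138, 25.87, 40.72 and 32.18 in T143, and 0, 0 and 18.24 in WT, where 0 allows up to 2.07 and 3.19. The strain label of every library names a Rag1 knockout, and these values do not settle the genotype of any group. Marker lists of further cell types gave these calls, in the order T143 against T138, T138 against WT and T143 against WT. Natural killer genes had 2, 5 and 7 of 10 higher and 0 lower. CD8 T cell genes had 2, 1 and 2 of 6 higher and 0, 1 and 0 lower, and gamma-delta T cell genes 1, 0 and 1 of 2 higher. B cell genes had 0 higher in each and 0, 0 and 1 of 11 lower. Thymocyte genes had 0, 1 and 1 of 7 higher and 1 lower in each. Stroma genes had 1, 1 and 0 of 9 higher and 2, 1 and 0 lower. Conventional CD4 genes had 5, 1 and 6 of 8 higher and 1, 3 and 0 lower. Dendritic genes had 0, 6 and 6 of 10 higher and 2, 0 and 0 lower, myeloid genes 4, 12 and 14 of 14 higher, and erythroid genes 3, 2 and 9 of 9 higher. The added neutrophil list had 12, 11 and 14 of 15 higher, and the added MHC class II list 5 of 7 lower, 7 higher and 7 higher.

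By chromosome, calls for T143 against T138 covered 4 of 4 tested genes on Y against 21.02% elsewhere (Fisher's exact test, adjusted p = 0.0412 over the chromosomes of that comparison). These are the Y-linked genes of the sex-linked list, absent or nearly absent in T143, so the result restates the sex difference. Among autosomes the lowest adjusted p was 0.0716, for chromosome 18 with 15.6% called against 21.18%. For T143 against WT it was 0.0666, for chromosome 17 with 27.78% against 23.54%. For T138 against WT it was 0.0974, for chromosome 8 with 8.05% against 11.2%. The same Y-linked genes were also called for T143 against WT, 4 of 4 against 23.74% elsewhere (Fisher's exact test, adjusted p = 0.0666).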
